A study of Mus musculus with 8 samples.

How the data were processed

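Total RNA in 8 samples of C2C12 cells, an established mouse myoblast line that fuses into myotubes when serum is withdrawn, was measured on 2-colour oligonucleotide arrays. Per the labels, 4 samples came from cells selected with a control retrovirus (Neo) and 4 from cells selected with a retrovirus that expressed HDAC4. All were grown to 90% confluence and kept in 2% horse serum for 4 days. Per the labels' protocols, 10 µg of RNA was DNase treated, each sample was labelled with Cy5 from oligo dT primers, and a murine reference RNA was labelled with Cy3 on every array. The same protocols name murine liver as the source of the reference. No array had the dyes swapped. Nothing in the labels says whether samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

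The authors deposited 1 log2 ratio per probe and array for 31769 probes. Background correction, normalization, filters and software are not given in the sources used here. The medians of the 8 deposited columns lay between 0.00576 and 0.0286, so the values had been centred or nearly so. A probe had a value on all 8 arrays in 14746 cases and on none in 7072 cases. The reason for missing values is not given in the sources used here.

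The direction of the ratio is not stated by the labels beyond the dyes. Genes of the contractile apparatus lay far above 0 on all 8 arrays, and the ratio was therefore read as cells over reference. This direction is likely rather than stated, and every signed value depends on it.

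The structure of the values was examined through 10 times the ratio. Values for which this was a whole number within 0.001 rose from 115 at 9 to 1921 at 10. This is the pattern of a reference signal set to a floor of 10 units, with the log2 ratio then holding the signal of the cells alone. Values at or above 10 units that met this tolerance are called values at the reference floor. The floor is inferred from the values and not stated in any label.

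Probes were named from the platform annotation that comes with the series. It listed 19380 of the probes, of which 18976 named 1 gene and 404 named several and were given no name. The other 12389 probes are unnamed here. Symbols were updated through the gene identifiers of the RefSeq table of assembly GRCm38.p6, used for names only. For 41 named probes the identifier was not in that table and the annotation's symbol was kept. No coordinates are given, because no build is named in the sources used here.

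Each array was centred on its median. A gene's value on an array was the mean over the probes that name it and no other gene. Probes without a single gene stayed as features of their own. Features needed at least 3 values in each group, which left 14750 features, 8741 of them named. HDAC4 was compared with Neo with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and p-values were adjusted with the Benjamini-Hochberg method at 0.05. Single genes also had an exact two-sided permutation test, whose smallest possible p with 4 against 4 arrays is 0.0286. The number of arrays limits the precision.

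The 18 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 17 lists with at least 3 tested members. Missing values, 1.69% of the cells of the matrix, were filled with the mean of their group for this test alone. Each list was also tested with an estimated correlation, and with fry. The design, the lists and the rule for named genes were fixed before the data were examined. The rule took every measured member of the dystrophin-glycoprotein complex. It took the 10 largest rises and 10 largest falls among named genes past the threshold whose groups did not overlap, or those that passed where there were fewer. It took the 4 members of each list with the smallest p. The part on largest changes was applied again to the fit with replicate 1 as a batch, a choice made after the data were seen. There, non-overlap was judged without the arrays numbered 1. That pair had to differ in the same direction where both arrays had a value, so the full groups of such genes may overlap.

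The replicate numbers were checked for pairing through the correlation, across features, of the deviations of same-numbered arrays from their group means. It was 0.51 for replicate 1, 0.28 for replicate 2, 0.17 for replicate 3 and 0.10 for replicate 4. All 4 values lay above the limit of 0.1 set beforehand, the last by a narrow margin (0.102), and by that limit alone the numbers were taken to pair the arrays. Differently numbered arrays of the 2 groups correlated as much in places: Neo replicate 2 with HDAC4 replicate 4 at 0.23, and Neo replicate 3 with HDAC4 replicate 4 at 0.20. HDAC4 replicates 3 and 4 correlated best with Neo replicate 2, so the pairing is not shown for numbers 3 and 4. Every differently numbered pair of the 2 groups without a replicate 1 had a positive value, from 0.06 to 0.23. Those of a replicate 1 with another number were all negative. A positive value may thus only reflect the arrays numbered 1 standing apart, and number 2 lies little above this range. The pairing comes from the values, since the labels give only the numbers. No 2 arrays held the same values: the SD of the difference between 2 arrays of a group was at least 0.34.

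Alternatives fixed beforehand were the values as deposited, quantile normalization, 2 other filters on missing values, each probe on its own, eBayes with a trend and robust variance, array weights, the replicate block, stricter thresholds, an unmoderated test and each array left out in turn. Alternatives chosen after seeing the data were replicate 1 as a batch, both arrays numbered 1 left out, and an offset removed from values at the reference floor. Others of this kind were no probes with values at the floor, batch and offset together, probes centred before averaging, and missing Dmd values set to the floor. The offset of an array was the median deviation of 152 probes that were at the floor on all 8 arrays and in none of the lists.

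The method was tested on simulated data for HDAC4 against Neo with 14750 features, 200 of them changed. It recovered 73% of the features changed by 1 log2 unit and 100% of those changed by 2 log2 units, with 11 false calls among 184, and made 0 calls without any change. These shares do not hold for every measured feature. In the planned limma fit, Casq2 and Ifit3 had changes of -3.20 and -2.23 with adjusted p of 0.674 and 0.595. Probes without a value on any array and features with too few values were left out of the fit. Figures were drawn with matplotlib 3.10.9.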

Results

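The study asked what a retrovirus expressing HDAC4, a class IIa histone deacetylase that binds the muscle transcription factor MEF2, does to gene expression in differentiated C2C12 muscle cells, with the dystrophin-glycoprotein complex in its title. RNA of 4 HDAC4 and 4 Neo control samples was compared, each array holding cells in one channel and a common reference in the other. The arrays differed in how many of the 31769 probes carried a value. Neo replicates 1 to 4 had 19248, 19907, 22193 and 21258 values, and HDAC4 replicates 1 to 4 had 17527, 17014, 18521 and 18312. The mean was 20652 ± 1325 (SD, n = 4) in Neo and 17844 ± 699 (SD, n = 4) in HDAC4, a difference with an exact permutation p of 0.0286, the smallest that 4 against 4 arrays allow.

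The direction of the ratio was read from genes of the contractile apparatus, so their high values are no separate result. The median log2 ratio over these genes was 5.72 ± 0.33 (SD, n = 8 arrays). The creatine kinase gene Ckm lay at 9.45 ± 0.35 (SD, n = 4) in Neo and 9.28 ± 0.25 (SD, n = 4) in HDAC4. Few liver probes carried a value. Of the 25 probes for the liver list, between 1 and 9 had a value on an array, and their median log2 ratio per array lay between 0 and 0.77. Of the values for liver genes, 51.5% were at the reference floor, the inferred minimum of the reference signal. They give no sign of liver transcripts in the reference, which a protocol in the labels names as liver. The values are few and the floor is inferred, so the source of the reference stays open.

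The 206 probes at the floor on all 8 arrays had a median change of -0.55 (HDAC4 minus Neo, log2; 95% bootstrap interval across probes -0.62 to -0.43), and 90.3% of them were lower in HDAC4. The 152 of them that belong to no gene list had a median of -0.56, and the 54 of listed genes had a median of -0.40 (95% bootstrap interval -0.66 to -0.23). Over arrays, the mean deviation of the 152 probes was 0.27 ± 0.24 (SD, n = 4) in Neo and -0.27 ± 0.26 (SD, n = 4) in HDAC4, with an exact permutation p of 0.0571. Neo replicate 1, at -0.0616, lay below HDAC4 replicate 4, at -0.0599, while within each of the 4 same-numbered pairs the HDAC4 array was lower. The 12775 probes never at the floor had a median change of 0.01, and the 22 of them in muscle lists had one of -0.13 (95% bootstrap interval -0.29 to 0.0036), with 68.2% lower. The change of floor probes was not the same at all levels: the median was -0.32 for 6 probes with a log2 ratio between 0 and 1, between -0.67 and -0.57 for those from 1 to 6, and -0.26 for 42 probes above 6. For a floor probe the value depends on the signal of the cells' channel alone. Most sarcomere genes are of this kind, with 77.3% of their values at the floor, against 38.5% for the dystrophin-glycoprotein complex, 56.5% for MEF2 targets and 1.88% for interferon genes.

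**Figure D1:**
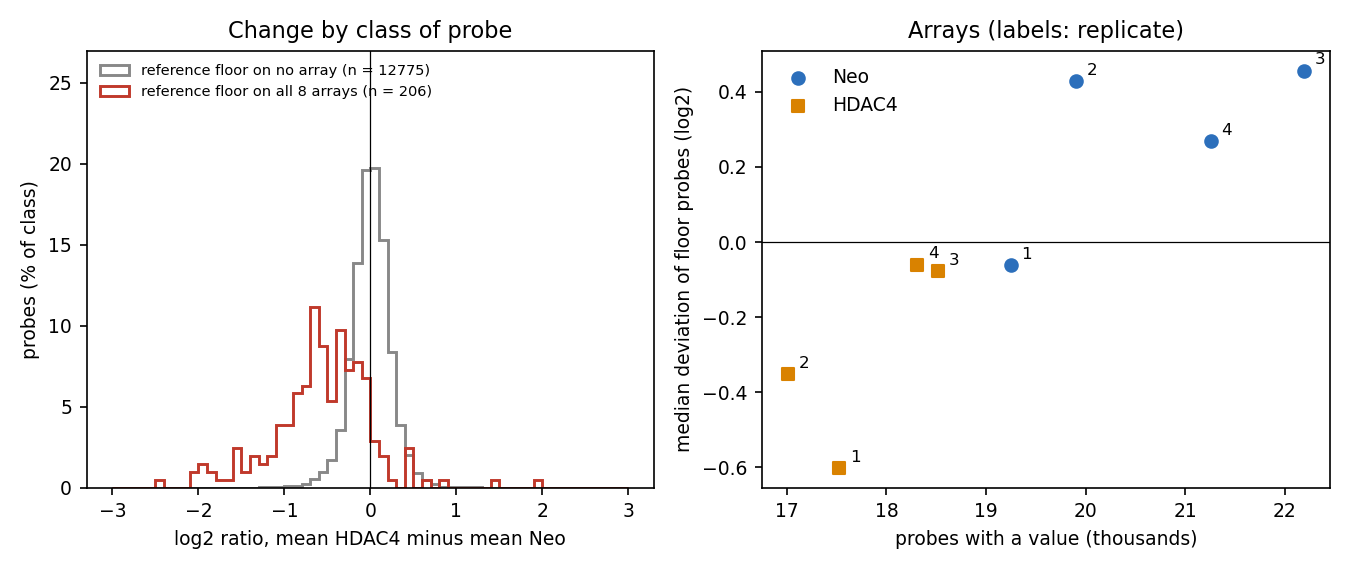
Left, the distribution of the change in log2 ratio (mean HDAC4 minus mean Neo) as a percentage of each class, for 206 probes at the reference floor on all 8 arrays and 12775 at the floor on none. Right, for each array, the median deviation of the 152 unlisted floor probes (log2) against the number of probes with a value. The 4 HDAC4 arrays have the fewest values, and the HDAC4 mean deviation is -0.27 against 0.27 in Neo.

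No probe is named for Hdac4 in the annotation used here, so the gene carried by the virus was not analysed here and the group labels were not checked against it.

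HDAC4 cells differed from Neo cells in 17 of 14750 features at an adjusted p under 0.05 in limma, 1 higher and 16 lower, and 11 of the 17 had a gene name. The interferon-inducible guanylate-binding protein gene Gbp8 was the one that rose, 4.51-fold (log2 change 2.17 ± 0.21, SE; adjusted p = 0.0158). It had 3 HDAC4 values, of which 2 were at the reference floor, and no Neo value at the floor, so the reference signal of this probe differed between the groups and the fold is uncertain. The interferon-inducible GTPase gene Igtp fell, with an expression 1.96-fold lower in HDAC4 (adjusted p = 0.0240) and no value at the floor. Of the muscle genes, Csrp3, a Z-disc protein of striated muscle, was 2.95-fold lower (log2 change -1.56 ± 0.18, SE; adjusted p = 0.0182). Mybpc2, the fast skeletal myosin-binding protein C, was 3.02-fold lower (adjusted p = 0.0364), and Abra, an actin-binding protein of striated muscle, was 2.53-fold lower (adjusted p = 0.0240). Txlnb was 2.65-fold lower (log2 change -1.40 ± 0.13, SE; adjusted p = 0.0126). The bone morphogenetic protein antagonist Nog was 2.84-fold lower (adjusted p = 0.0158), and the apolipoprotein gene Apod was 5.07-fold lower (adjusted p = 0.0372). Apod had no value on Neo replicate 1, and its log2 change of -2.34 was -2.10 without the arrays numbered 1. Misp3, Enho and the collagen gene Col24a1 were 3.90-fold, 2.34-fold and 2.60-fold lower, with adjusted p of 0.0158, 0.0240 and 0.0278. All 11 named genes had groups that did not overlap. Over the tested features, 5.32% had non-overlapping groups, against 2.86% for chance with 4 values in each.

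Of the 17 features, 14 had most of their values at the reference floor, and with the floor offset removed 4 features passed, 3 higher and 1 lower. These were Gbp8, the acetylcholine receptor subunit Chrng and the unnamed probe M200004629, all higher, and the unnamed probe M200008363, lower. Chrng lies above a log2 ratio of 6, where floor probes changed by -0.26 and not by the offset of -0.55. Its rise in that fit may therefore be overstated. The unnamed probes were singled out after their values were seen, and Gbp8 and M200008363 are among the 17. With the replicate number as a block, which leaves 3 residual degrees of freedom against 6, 9 features passed and 1746 had an unadjusted p under 0.05, against 1082 in the planned fit. Of the 9, 7 are among the 17, including Txlnb, Misp3, Col24a1, Abra and Gbp8. The other 6 named genes, Csrp3, Mybpc2, Nog, Apod, Igtp and Enho, had adjusted p between 0.0573 and 0.0715 with the block. With the offset removed, the 10 named genes other than Gbp8 had adjusted p between 0.0603 and 0.608. The change of Igtp stayed at -0.97 and that of Misp3 went from -1.96 to -1.81, so a shift at the floor did not end these calls through a smaller change. The other 8, with most values at the floor, went from between -2.34 and -1.23 to between -1.68 and -0.79. The count was 65, 0, 0 and 0 without Neo replicate 1, 2, 3 and 4, and 73, 4, 5 and 2 without HDAC4 replicate 1, 2, 3 and 4. At an unadjusted p under 0.05 in limma, those 3 counts of 0 stood at 865, 911 and 903 features.

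The arrays numbered 1 stood apart from the rest in both groups. Their log2 ratios correlated across probes at 0.94 with each other and at no more than 0.90 with any other array, while any 2 of the other 6 arrays correlated at 0.93 or more. With replicate 1 as a batch, 2978 features differed between these arrays and the others. In that fit 92 features differed between HDAC4 and Neo, 20 higher and 72 lower, and all 17 features of the planned fit were among them. Of the 92, 50 had most of their values at the floor, and with batch and floor offset removed 55 features differed, 29 higher and 26 lower. Without both arrays numbered 1, 291 features differed, 88 higher and 203 lower. Within the pair numbered 1 there was 1 array per group and no test.

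In the fit with the batch, Cdkn1c, the cyclin-dependent kinase inhibitor p57, rose 3.84-fold (log2 change 1.94 ± 0.20, SE; adjusted p = 0.01004). The transcription factor gene Mef2a, itself a partner of class IIa deacetylases, had a log2 change of 1.15 ± 0.17 (SE; adjusted p = 0.0283), and the serine protease gene Htra3 one of 1.58 (adjusted p = 0.0147). Porcn, which acylates Wnt proteins, Mycl, Inpp5j, Blnk and Stac2 also rose, by log2 changes between 0.65 and 1.29. Aldh3b1 had a gene value of 1.27 (adjusted p = 0.0125), but its only probe measured in both groups differed by 0.24, since a weaker probe had values on the Neo arrays alone. On the side of the falls, Slc2a4, the insulin-responsive glucose transporter GLUT4, changed by -1.82 ± 0.21 (SE; adjusted p = 0.0131) and the fast myosin heavy chain gene Myh2 by -1.42 ± 0.12 (SE; adjusted p = 0.00625). Ifit3, an interferon-induced gene, changed by -2.23 ± 0.24 (SE; adjusted p = 0.0106), Art5 by -1.98 (adjusted p = 0.0249) and Cfap52 by -1.41 (adjusted p = 0.0200). With the offset removed as well, Myh2 (-0.88, adjusted p = 0.0607), Art5 (-1.43, 0.0956) and Cfap52 (-0.86, 0.0993), all at the floor, did not pass. In the planned fit without the batch, these 14 genes had adjusted p between 0.0568 and 0.750. With the replicate number as a block Myh2 passed (adjusted p = 0.0379) and the other 13 did not (0.0573 to 0.127).

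The dystrophin-glycoprotein complex, which links the cytoskeleton of muscle fibres to the basal lamina, was lower in HDAC4 as a list, by a small amount. Of 13 tested members 10 were lower and 3 higher, with a median log2 change of -0.20 (camera adjusted p = 0.0226). With an estimated correlation of 0.0032 between members, below the preset 0.01, the adjusted p was 0.172, and with fry 0.0398. The title of the study gives this direction, so the list was not chosen blind to it. Over all features 0 members passed in limma, with 3 lower and 0 higher at an unadjusted p under 0.05, and adjusted over the list alone 1 passed. That member was Cav3, the muscle caveolin, at 7.35 ± 0.33 (SD, n = 4) in Neo and 6.25 ± 0.30 (SD, n = 4) in HDAC4, 2.14-fold lower (adjusted p = 0.125 over all features, exact permutation p = 0.0286). All values of Cav3 were at the reference floor. With replicate 1 as a batch its adjusted p was 0.01004, with the replicate number as a block 0.0573, and with batch and offset 0.141.

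The sarcoglycan genes differed by less than Cav3, and neither passed. Sgcd had a log2 change of -0.39 ± 0.14 (SE; adjusted p = 0.561) and Sgcb one of -0.30 ± 0.12 (SE; adjusted p = 0.607). Neither had values at the floor, and in both the 4 HDAC4 arrays lay below the 4 Neo arrays. Sgce had a change of -0.11 ± 0.15 (SE). The intracellular members gave -0.49 for Sntb1, -0.40 for Dtna, -0.22 for Dtnb, 0.12 for Sntb2 and -0.06 for Nos1 (0.21 with centred probes), and adjusted p of 0.724 or more. Dtna averages probes that went opposite ways, at 0.23 and -1.03. The second of these had 3 HDAC4 values at the floor and 0 Neo values there. With 1 array left out, Dtna ranged from -0.61 to -0.15, Sntb2 from 0.04 to 0.25 and Nos1 from -0.52 to 0.18. Dystroglycan (Dag1) had a change of 0.20 ± 0.19 (SE), sarcospan (Sspn) 0.10, utrophin (Utrn) -0.07 and the laminin chain Lama2 -0.20. Leaving out 1 array gave ranges of 0.03 to 0.17 for Sspn, -0.20 to 0.10 for Utrn and -0.30 to -0.07 for Lama2. Lama2 rests on 6 probes with different levels and missing values, and its 5 probes measured in both groups gave differences between -0.63 and -0.17. With the floor offset removed, Sntb1, Lama2 and Nos1 changed sign, to 0.06, 0.33 and 0.13, and Cav3 had a change of -0.55. Cav3 lies above a log2 ratio of 6, where floor probes changed by -0.26, so the constant offset may remove too much there. With the offset removed, 7 of the 13 members were lower and 6 higher (camera adjusted p = 0.541). Without probes at the floor, which left 8 members and not Cav3, the adjusted p was 0.444. It was 0.0712 with at least 2 values per group, 0.0726 with each probe on its own and 0.0614 without both arrays numbered 1. The adjusted p also lay above 0.05 without Neo replicate 2 (0.105), Neo replicate 3 (0.0687) or HDAC4 replicate 1 (0.0781).

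**Figure D2:**
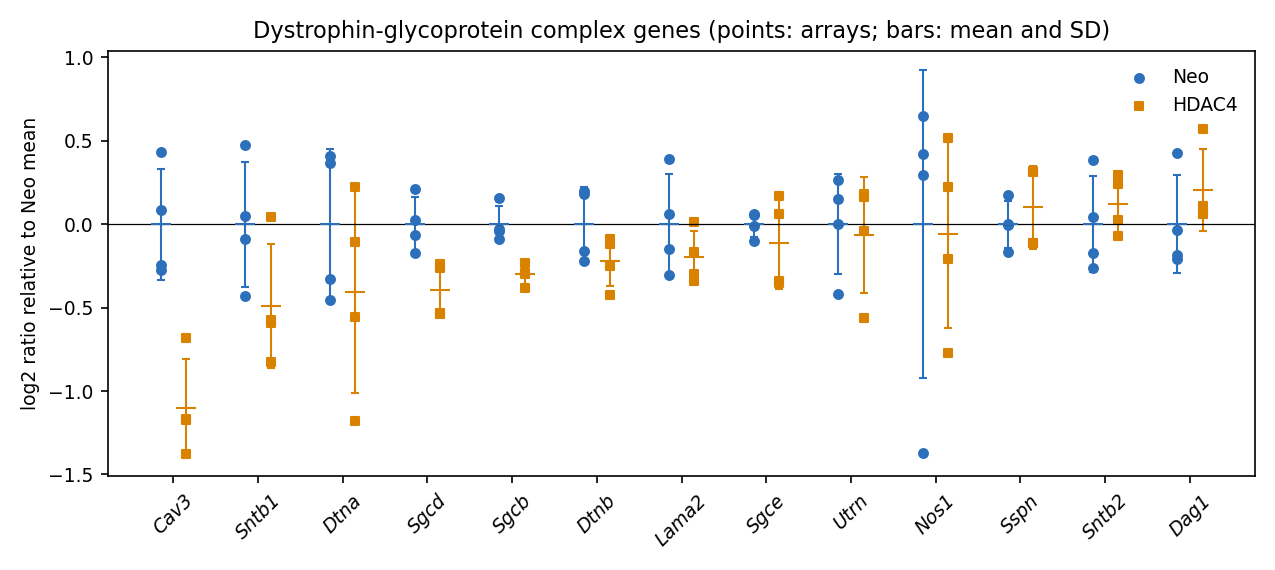
Log2 ratio of 13 genes of the dystrophin-glycoprotein complex relative to the gene's Neo mean, with 1 point per array and the mean and SD of each group. Cav3, Sgcd and Sgcb have HDAC4 arrays all below the Neo arrays; Dag1, Sspn and Sntb2 have HDAC4 means above 0.

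Dystrophin itself was seen in Neo and mostly not in HDAC4. Dmd had 5 probes, of which 3 had no value on any array and 2 had values at the reference floor. The first of the 2 stood at 17, 17, 13 and 15 units in Neo replicates 1 to 4 and had no value on any HDAC4 array. The second stood at 21, 21, 21 and 22 units in Neo and at 17 units in HDAC4 replicate 1, with no value on the other HDAC4 arrays. Neither passed the planned filter, so limma gave no test. Presence of a value differed between the groups with a Fisher's exact p of 0.0286 for the first probe and 0.143 for the second, tests made because the values were missing. The measured values of the second probe differed by -0.32 (log2, 4 Neo values and 1 HDAC4 value). No fold is given, as the reason for missing values is unknown. Sgcz, Sntg1 and Sntg2 had too few values to be tested.

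Sarcomere genes, which build the contractile apparatus, were lower in HDAC4 as a list. Of 30 tested members 27 were lower, with a median log2 change of -0.37 (camera adjusted p = 3.8e-09, 0.00625 with an estimated correlation, and 1.9e-04 with fry). Over all features 2 members passed, Csrp3 and Mybpc2, and adjusted over the list alone 7 passed, all lower. Csrp3 and Mybpc2 did not pass with the replicate block (adjusted p = 0.0650 and 0.0573) or with the floor offset removed (0.238 and 0.249). Pdlim3, a Z-disc protein, had a log2 change of -0.93 ± 0.14 (SE; adjusted p = 0.0561), and Myh2 one of -1.42 ± 0.23 (SE; adjusted p = 0.0794). MEF2 target genes gave a median change of -0.28, with 12 of 17 members lower (camera adjusted p = 5.7e-04, 0.172 with an estimated correlation, and 0.0398 with fry). Myoz2, Myom1, Acta1, Actn3, Myl1, Myh7 and Lmod3 are in both the MEF2 and the sarcomere list, so the results of these lists are not independent. None of the 17 passed over all features in limma, with 6 lower and 0 higher at an unadjusted p under 0.05, and 5 passed adjusted over the list alone. They were Srpk3, a muscle protein kinase, with a change of -1.23 ± 0.18 (SE), Slc2a4, Xirp1 with -1.07 ± 0.27 (SE), the sarcomere gene Myoz2 with -0.93 ± 0.29 (SE), and the myoglobin gene Mb with -0.91 ± 0.30 (SE). With the floor offset removed, Pdlim3 and Myh2 had changes of -0.39 and -0.88, and Srpk3, Slc2a4, Xirp1, Myoz2 and Mb had -0.69, -1.27, -0.53, -0.44 and -0.36. Ckm, Myog and Des, chosen from the same list after their values were seen, had changes of -0.17, 0.19 and 0.02 in the planned fit, and of 0.38, 0.73 and 0.52 with the offset removed. Ckm lies above a log2 ratio of 6, where the constant offset may remove too much. With the floor offset removed the adjusted p was 0.387 for the sarcomere list, with 16 members lower and 14 higher, and 0.541 for MEF2 targets, with 11 lower and 6 higher. Without probes at the floor, which left 3 sarcomere genes and 5 MEF2 targets, both adjusted p were 0.971. Without the arrays numbered 1 the adjusted p was 0.109 for MEF2 targets.

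**Figure D3:**
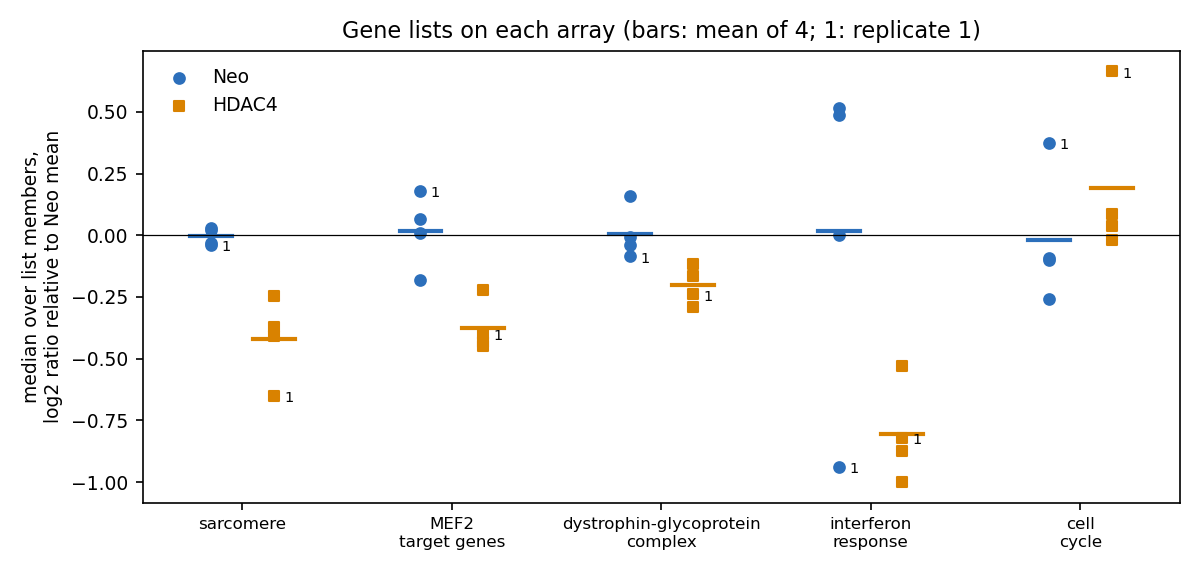
Median over the members of 5 gene lists on each array, as log2 ratio relative to the gene's Neo mean, with bars at the mean of 4 arrays and replicate 1 marked. Sarcomere medians lie between -0.65 and -0.25 on HDAC4 arrays and between -0.04 and 0.03 on Neo arrays, while Neo replicate 1 lies among the HDAC4 arrays for interferon genes, at -0.94.

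Other muscle lists gave no call. For myogenic transcription factors, 8 of 13 members were lower (camera adjusted p = 0.630), and adjusted over the list alone 2 passed. These were Myf6, a late myogenic factor, with a log2 change of -0.88 ± 0.20 (SE; adjusted p = 0.223 over all features), and Id1, an inhibitor of myogenic factors, with -0.70 ± 0.16 (SE; adjusted p = 0.237). All values of Myf6 were at the floor, and with the offset removed its change was -0.33. Mef2a was 2.21-fold higher (adjusted p = 0.581 without the batch), and Tead4 had a change of 0.38. Myoblast fusion and adhesion genes (camera adjusted p = 0.975) had a median change of 0.04 and a mean of -0.04, with the test on the lower side. Cav3 and the adhesion molecule gene Jam2, which had a change of -1.37 ± 0.27 (SE), passed adjusted over the list alone (changes of -0.55 and -0.89 with the floor offset removed), and Cd9 and Itgb1 had changes of -0.33 and -0.34.

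Neuromuscular junction genes had a median change of 0.06 and a mean of -0.06, with the test on the higher side (camera adjusted p = 0.930). The fetal acetylcholine receptor subunit Chrng had a change of 0.69 ± 0.18 (SE) and the transcription factor gene Etv5 one of -0.48 ± 0.13 (SE), and both passed adjusted over the list alone. Chrnb1 had a change of 0.44 and Ache one of -0.86 (-0.43 with the floor offset removed). With the floor offset removed, 11 of these 15 genes were higher and the list passed as higher (camera adjusted p = 0.0480). Chrng then had a change of 1.12. Above a log2 ratio of 6, where Chrng lies, the constant offset may remove too much, so this call is uncertain. In excitation-contraction coupling (camera adjusted p = 0.371), 10 of 18 members were lower. Jsrp1, a junctional protein of the sarcoplasmic reticulum, had a change of -0.88 ± 0.19 (SE) and passed adjusted over the list alone, while Casq2 at -3.20 ± 1.38 (SE), Trdn at -0.95 and Cacna2d1 at -0.57 did not. Casq2 on HDAC4 replicate 1 (7.74) lay within the Neo values. Its change was -5.11 without that array (adjusted p = 0.0494) and -2.0 without HDAC4 replicate 2. With the floor offset removed the changes of Jsrp1, Casq2 and Trdn were -0.33, -2.65 and -0.41. That of Trdn in the planned fit ranged from -1.38 without HDAC4 replicate 2 to -0.63 without HDAC4 replicate 3. With each probe on its own this list passed as lower (adjusted p = 0.0394).

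Interferon response genes gave the largest median change of any list, -0.95, with 19 of 20 members lower in HDAC4 (camera adjusted p = 3.8e-09). With an estimated correlation of 0.55 between members the adjusted p was 0.389, and with fry, which tests whether a list's genes move 1 way on balance, it was 0.264. Over all features 0 members passed in limma, with 8 lower and 0 higher at an unadjusted p under 0.05, and adjusted over the list alone 0 passed. Oas2 had a log2 change of -1.32 ± 0.33 (SE; -0.84 with centred probes), Usp18 one of -1.62 ± 0.45 (SE), Cxcl10 one of -1.22 ± 0.41 (SE) and Ifit3 one of -2.23 ± 0.83 (SE). The list's median on Neo arrays, relative to the Neo mean, was -0.94 in replicate 1 and between 0.00 and 0.51 in the others, against values from -1.0 to -0.53 on HDAC4 arrays. Without the arrays numbered 1, 19 of 20 members were lower, with a median of -1.18 (adjusted p = 1.0e-15).

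Cell cycle genes were slightly higher in HDAC4, with 30 of 37 members higher and a median change of 0.24 (camera adjusted p = 9.2e-04). With an estimated correlation of 0.47 between members the adjusted p was 0.727, and with fry 0.609. No member passed over all features or over the list alone in limma, and 2 were higher and 0 lower at an unadjusted p under 0.05. These were the replication licensing genes Mcm3, with a change of 0.45 ± 0.16 (SE), and Mcm2, with 0.32 ± 0.13 (SE). Ccna2 and Aurka gave 0.60 and 0.46. The list was also higher on the arrays numbered 1 than on the others, by a median of 0.62 (adjusted p = 2.6e-08). At the preset correlation, quantile normalization gave a camera adjusted p of 0.0601. Leaving out HDAC4 replicate 1, with Neo replicate 1 kept, gave 0.494, and leaving out both arrays numbered 1 gave 4.8e-04.

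Metabolic, adhesion and matrix lists were not called. In glycolysis and phosphagen metabolism (camera adjusted p = 0.669), the median was 0.03 and the mean -0.11, with the test on the lower side. Slc2a4 and the lactate dehydrogenase gene Ldhb, at -0.61 ± 0.15 (SE), passed adjusted over the list alone, while Pfkm had a change of -0.39 and Slc2a1 one of 0.38. Oxidative phosphorylation genes were split, 32 lower and 27 higher (camera adjusted p = 0.942), with Cyc1 at 0.31, Ndufa9 at 0.31, Cox7b at -0.24 and Cox8b at -0.79 (-0.25 with the floor offset removed). For the costamere and integrin list (camera adjusted p = 0.630), Lama4 had a change of -0.57 (-0.02 with the floor offset removed), Capn3 one of -0.74, Nid1 one of 0.31 and Itgb1 one of -0.34. In the extracellular matrix list, 16 members were lower and 15 higher (camera adjusted p = 0.669). Col18a1, the collagen whose fragment is endostatin, was 2.31-fold higher and passed adjusted over the list alone (adjusted p = 0.172 over all features). Postn, Col4a1 and Loxl1 had changes of -0.72, -0.50 and 0.45. Without the arrays numbered 1, 22 matrix genes were lower and the list passed as lower (adjusted p = 0.00665, and 0.00587 with array weights).

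Markers of other lineages and stress genes gave no call either. For adipocyte markers 4 of 6 tested members were lower (camera adjusted p = 0.669), with Dgat2 at -0.33, Pparg at -0.18 (0.04 with centred probes), Lpl at -0.19 and Scd1 at -0.11. For bone and cartilage markers 3 of 5 were lower (camera adjusted p = 0.930), with Sox9 at 0.59 ± 0.19 (SE), Acan at -0.42, Alpl at -0.45 and Bmp4 at -0.35. With 1 array left out, Alpl ranged from -0.76 to -0.21 and Bmp4 from -0.72 to -0.06. Atrophy and autophagy genes, with Sesn1 at -0.49, Fbxo30 at -0.34, Map1lc3a at 0.25 and Ube2d1 at 0.26, had a camera adjusted p of 0.930. The unfolded protein and heat shock list had the same adjusted p of 0.930, with Atf3 at -0.86, Hspb2 at -0.50 (-0.10 with the floor offset removed), Hsp90aa1 at 0.25 and Hspb8 at 0.15. Of the liver list only Ahsg was measured often enough, with a change of -0.21 ± 0.21 (SE; 0.09 with the floor offset removed), and the list was not tested.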

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

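Tests chosen after their result was seen are those on unlisted floor probes, Dmd, the interferon genes without the arrays numbered 1 and at the floor, and a mislabelled array. The offset and the batch were themselves chosen after seeing the data.

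In 26 of 176 groups of arrays tested, 1 array stood far from the other 3, where chance gives about 1 in 20 groups. In 23 of the 26 it was an array numbered 1. Genes chosen through the batch fit favour such cases; without those 20 genes, 17 of 134 groups of gene values did so, 14 of them through an array numbered 1. Neo replicate 1 held such log2 ratios for Bmp4 (-2.62), Cdkn1c (2.16), Col24a1 (2.12), Enho (4.11), Myh2 (5.64), Usp18 (-3.80) and Xirp1 (6.17). HDAC4 replicate 1 held them for Aldh3b1 (1.402), Aurka (-2.24), Blnk (-2.81), Bmp4 (-2.72), Cacna2d1 (2.36) and Cd9 (-0.0452). It also held them for Cdkn1c (3.23), Cyc1 (2.21), Dag1 (1.81), Fbxo30 (0.22), Id1 (-1.67), Inpp5j (1.78), Map1lc3a (2.78), Mycl (-5.22) and Porcn (2.76). Acan in Neo replicate 3 (-0.0707), Map1lc3a in Neo replicate 4 (2.68) and Usp18 in HDAC4 replicate 2 (-3.53) were the others among genes. The SD of all log2 ratios of Neo replicate 1 was 1.396, against 1.28 to 1.29 on the other Neo arrays. Among probes outside the test, 2 had a value on all 4 HDAC4 arrays and on no Neo array, Nqo2 (mean log2 ratio 0.47) and the unnamed M300020564 (0.35).

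The arrays numbered 1 deviated from the rest of their groups in the same way, with a correlation of 0.522 across genes, which argues against a single mislabelled array. The level of a gene explained 0.00239% of the variance of the difference, which argues against a different scale of the ratios. Interferon genes stood at a median of -0.94 on Neo replicate 1 and -0.82 on HDAC4 replicate 1, so this pair narrows the difference between the groups and cannot be its whole cause; leaving it out, with 95% of members lower, could only widen the difference and adds nothing. With 1.88% of their values at the floor, the floor is argued against as its whole cause. For the difference between the groups, an effect of HDAC4 on interferon genes and a difference in interferon signalling between samples stay open. A batch shared by the 2 arrays numbered 1 stays open only for the low values of that pair, since the labels give no batch.

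Sarcomere, MEF2 target and dystrophin-glycoprotein genes were lower in HDAC4, and so were floor probes outside the lists, by a median of -0.56. The fall was thus not limited to the listed genes. Those unlisted probes include the striated muscle gene Abra, with a change of -1.34, so a fall of muscle genes may be part of the offset. With the offset of the unlisted probes removed, the camera adjusted p was 0.387, 0.541 and 0.541. A lower signal of the cells' channel on HDAC4 arrays at the floor would give this. So would a fall of unlisted muscle genes. The mean change over members went from -0.58 to -0.13 (SD 0.59) for sarcomere genes, from -0.46 to -0.13 (SD 0.51) for MEF2 targets and from -0.22 to -0.07 (SD 0.27) for the complex, so the calls ended through smaller means. The MEF2 median hardly moved, from -0.28 to -0.26, and its 11 members mostly at the floor still had a median of -0.44, so the offset may account for part of that list only. Both explanations stay open, since removing an offset taken from probes that include a muscle gene cannot tell them apart. A constant offset of -0.55 may also remove too much above a log2 ratio of 6, where floor probes changed by -0.26. The offset, lower in HDAC4 in all 4 same-numbered pairs, had an unpaired exact permutation p of 0.0571.

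More probes lacked a value on HDAC4 arrays: 166 had values on all 4 Neo arrays and no HDAC4 array, against at most 101 for any other split. Of floor probes above 4 times the floor in Neo, 3.08% (7 of 227) had a value on at most 1 HDAC4 array. The share was 72.7% (8 of 11) nearest the floor. It was 40.6% (13 of 32) at log2 ratios from 0.5 to 1 and 24.4% (11 of 45) from 1 to 1.5. A lower signal that drops weak probes would give such a fall with level. Lower expression would do so too, so the fall cannot tell these apart. At the level of Dmd, 30.6% of floor probes had a value on at most 1 HDAC4 array, against 1.92% in reverse. The missing Dmd values are thus shared with many probes of its level, and lower Dmd expression in HDAC4 cells stays open beside the lower signal.

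Over all 35 splits of the arrays, which ignore the pairing, the real one alone gave as many as 17 changed features, and the highest other gave 2. The real split was also the only 1 of 35 as extreme for the sarcomere list (camera p 2.6e-10, smallest other 9.9e-06) and the dystrophin-glycoprotein list (0.00665, smallest other 0.00959, which is close). Chance was not excluded for interferon genes, where 5 of 35 splits gave a camera p as small as the real 4.5e-10. The smallest other was 1.4e-18, for Neo replicate 1 and HDAC4 replicates 1, 3 and 4 against the rest. That value points to a structure of the samples. The replicate block gave a camera adjusted p of 1.8e-10 at the preset correlation of 0.01. In the planned fit, the list's estimated correlation of 0.55 gave 0.389. Chance was also not excluded for MEF2 targets (2 of 35 splits, 1.0e-04, smallest other 2.4e-06) or cell cycle genes (13 of 35 splits, 2.2e-04, smallest other 3.3e-12). Among the 8 splits that part all 4 pairs, the real one alone was as extreme for the count, sarcomere, MEF2 and dystrophin-glycoprotein lists, and 2 were for cell cycle and for interferon genes. With the pairing kept, which the values do not show for numbers 3 and 4, 8 splits cannot give a share under 0.05. With replicate 1 as a batch, 1 of 20 splits gave the real count of 92 and the highest other gave 5, but 20 splits cannot give a share under 0.05.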

How the results depend on the processing

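Alternatives with replicate 1 as a batch, without both arrays numbered 1, with the floor offset removed, without probes at the floor, with batch and offset, and with centred probes were chosen after seeing the data. The count of 17 features was 456 with array weights, 9 with the replicate block, 92 with the batch, 291 without both arrays numbered 1, 4 with the offset removed and 55 with batch and offset (29 higher, 26 lower). In limma it was 0 without probes at the floor, where 776 features had an unadjusted p under 0.05, and 0 at an adjusted p under 0.01, where the main 1082 had one. It was 1 without moderation, and from 0 to 73 with 1 array left out. The replicate block changed no call of a gene list.

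For the dystrophin-glycoprotein complex the adjusted p was 0.0712 with at least 2 values per group, 0.0726 with each probe on its own and 0.172 with an estimated correlation. It was 0.0614 without both arrays numbered 1, 0.541 with the offset removed, 0.444 without floor probes, 0.643 with batch and offset, and from 0.0127 to 0.105 with 1 array left out. For sarcomere genes it was 0.387 with the offset removed, 0.971 without floor probes and 0.731 with batch and offset. For MEF2 targets the values in the same order were 0.541, 0.971 and 0.643, with 0.172 for an estimated correlation and 0.109 without both arrays numbered 1. Neuromuscular junction genes passed as higher with the offset removed (0.0480) and with batch and offset (0.0290), where the offset may remove too much above a log2 ratio of 6. Excitation-contraction coupling passed as lower with each probe on its own (0.0394) and with centred probes (0.0389), and extracellular matrix with array weights (0.00587) and without both arrays numbered 1 (0.00665). Cell cycle genes had 0.0601 with quantile normalization, 0.727 with an estimated correlation and from 2.9e-07 to 0.494 with 1 array left out, and interferon genes had 0.389 with an estimated correlation. The sarcomere level was 4.80 per probe in place of 5.72, and the second Dmd probe, with 3 of 4 HDAC4 values assumed to be at the floor and so no measured change, gave -0.90 and, with the offset removed, -0.35. Causes were not tested, except that floor alternatives remove floor values or their offset by construction.

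Of 390 values for gene lists under alternatives, 362 kept their side of the threshold, 22 no longer passed, 6 newly passed and 0 called ones reversed. Uncalled values changed sign in 40 cases. Among the 94 named genes no called direction reversed in any setting. Hdac4 and Dmd had no value in the planned test. Missing values near the floor limit what weak probes can show.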

Other observations

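With replicate 1 as a batch, chosen after seeing the data, further genes differed between HDAC4 and Neo. The late myogenic factor Myf6 had a log2 change of -0.88 ± 0.15 (SE; limma adjusted p = 0.0495), and Id1 one of -0.70 ± 0.10 (SE; adjusted p = 0.0256). Srpk3 changed by -1.23 ± 0.18 (SE; adjusted p = 0.0265) and Pdlim3 by -0.93 ± 0.12 (SE; adjusted p = 0.0196). None of these 4 genes passed with the replicate number as a block (adjusted p between 0.0573 and 0.159). With batch and offset together, Id1 passed (0.0429), while Srpk3 (-0.69, 0.163), Pdlim3 (-0.39, 0.249) and Myf6 (-0.33, 0.456), all at the floor, did not. In that fit Cdkn1c, Mef2a, Slc2a4, Ifit3 and Igtp passed, with adjusted p of 0.0116, 0.0429, 0.0429, 0.0213 and 0.0211, while Cav3 (0.141), Csrp3 (0.0607) and Myh2 (0.0607) did not.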
